A study of Mus musculus with 38 samples.

How the data were processed

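Knee joints of mice of the inbred strains LG/J and SM/J were measured with QuantiGene Plex, a bead-based branched-DNA assay that reads transcripts directly from tissue lysates without amplification. Per the labels, LG/J mice are healers and SM/J mice are non-healers, the lysates came from formalin-fixed, paraffin-embedded sections, and the mice had a full-thickness articular cartilage repair operation at 8 weeks of age. The sources used here do not say which knee was operated on. There were 5 mice per strain and 19 knees, since SM/J mouse 2 had a right knee in the files and no left knee was analysed. Each knee was read in 2 technical replicates, which gives 38 wells.

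The deposited signal table holds the fluorescence intensity of 80 genes per well, with 4 blank wells and, from the values, no background subtraction. Blank wells read from 3 to 113.5 units. Assay depth in the sense of counts does not apply; signal over the blank and the number of knees limit the precision. Of the 78 tested genes, 23 had a median signal below 3 times the median blank. The deposited normalized table is on a log10 scale, which the authors' values themselves show: each value equals the log10 signal minus an intercept and a slope for each of log10 Gapdh and log10 Hprt, with a separate set for every gene. The slopes were not those fitted to these 38 wells, and their origin is not given in the sources used here. A further table, the authors' deposited table of strain means, holds log10 means over 18 SM/J and 20 LG/J wells and a column headed fold change. No reader software and no genome build is given in the sources used here.

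The deposited log10 values were converted to log2 by the factor 3.32, and the technical replicates were averaged to a single value per knee. The median technical SD over genes was 0.12 and the median SD between mice of a group was 0.19, both in log2 units, and no wells held identical values. Groups were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over 78 genes and a threshold of 0.05. Gapdh and Hprt were not tested as outcomes there. The strain comparison over both knees had side as a term and mouse as a random block (duplicateCorrelation, statmod 1.5.0). Right and left knees of a mouse were compared with mouse as a replicate block, and the strain difference in the right-left difference was tested on the differences per mouse. These knees are paired because the labels give each animal's number; deviations of the paired knees correlated across genes from -0.10 to 0.49 in SM/J and from -0.21 to 0.50 in LG/J. List scores, the mean log2 value over at least 3 measured members of a gene list, were compared by exact permutation or exact sign-flip tests, two-sided, with Benjamini-Hochberg adjustment over 9 scores. The main tests and the gene lists were fixed before the data were examined. The planned step for values at or below 0 was not needed, since the table already is on a log scale.

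Of the 10 gene lists fixed beforehand, 6 had a tested member. Lists for housekeeping genes, inflammation and cytokines, macrophages and osteoclasts, and muscle, fat, blood and vessel had 0 tested members. Named genes were those past the threshold, or the 25 largest by size of log2 difference where more passed; where fewer than 10 passed, those with the smallest p up to 10 were added, as were up to 4 members of each list. Of the panel, 77 genes matched a mouse RefSeq table (GRCm38.p6), 72 by current symbol and the rest by synonym; it served for names and for which genes neighbour each other. GOs2 is kept as spelled in the files. All 78 genes entered the tests and counts, and some results are not reported here.

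The fits were tested on simulated data of 78 genes in independent knees with 20 changed by 1 log2 unit. The right-knee strain fit recovered 20 with 2 false calls, the left-knee fit 19 with 1, and the fit over both knees 20 with 2. The SM/J side fit recovered 18 with 0 false calls, the LG/J side fit 20 with 0, the side fit over both strains 20 with 1, and the fit of the strain difference in the right-left difference 20 with 2. A change of 1 log2 unit is large against the median SD of 0.19 between mice of a group. Recovery of smaller differences, such as many of those reported below, was not tested. Alternatives covered signals scaled by Gapdh and Hprt, unscaled or centred on the well median, a low-signal filter, each technical replicate, linear averaging, exact permutation, robust limma, the blocks and leaving out each mouse. Added after seeing the data were fits with Gapdh and Hprt as covariates, with and without blank subtraction, centring of the deposited values, and splits by Hprt signal. Figures were drawn with matplotlib 3.10.9.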

Results

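Transcripts of 78 genes, plus the normalizers Gapdh and Hprt, were measured in 19 knees: 5 right and 5 left knees of LG/J mice, and 5 right and 4 left knees of SM/J mice. Values are normalized log2 expression, and differences are given with their SE from limma. Gapdh signal varied 6.03-fold over the knees and Hprt signal 19.5-fold. In right knees Hprt signal was 3.15-fold higher in LG/J mice (exact permutation p = 0.0714, adjusted p = 0.262, n = 5 per strain) and Gapdh signal 2.11-fold higher (exact permutation p = 0.0873, adjusted p = 0.262), and neither passed adjustment over 12 such tests.

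**Figure D1:**
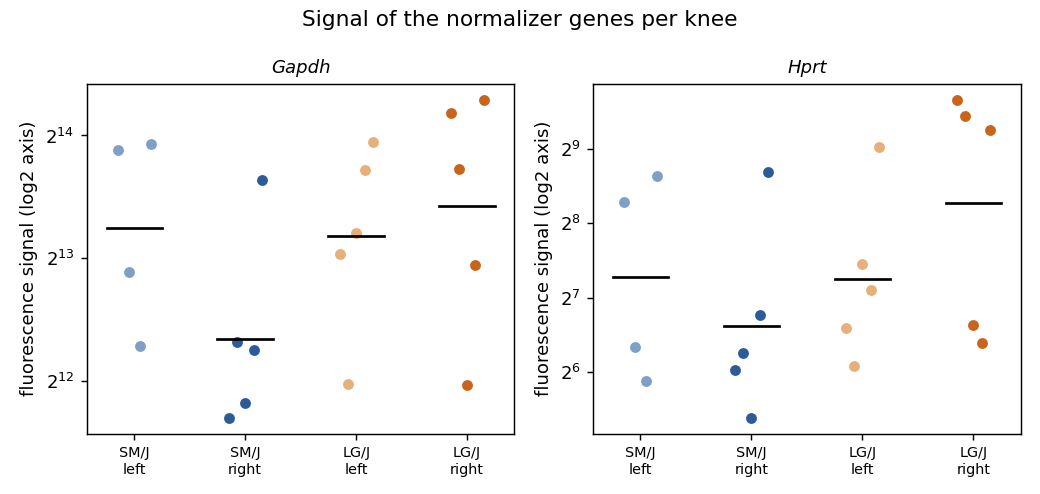
Fluorescence signal of Gapdh and Hprt per knee on a log2 axis, by strain and side; points are knees and bars geometric means. Knees of every group spread widely, with a 19.5-fold range for Hprt.

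The first comparison asked which genes differ between a healer and a non-healer strain in the right knee. Acan, which encodes aggrecan, the main proteoglycan of cartilage, was 2.00 ± 0.28 log2 units higher in LG/J than in SM/J right knees (adjusted p = 0.000475, n = 5 per strain). Comp, a cartilage matrix protein, was 1.37 ± 0.41 higher (adjusted p = 0.0241). Stab2, a scavenger receptor for hyaluronan, was lower by -1.44 ± 0.23 (adjusted p = 0.000616). In all, 32 of 78 genes passed, 26 higher and 6 lower in LG/J.

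Among cartilage matrix genes, 2 of 3 passed as higher in the right knee and 2 passed when adjusted over the list alone; Col2a1, the main collagen of cartilage, differed by -0.01 and did not pass, though with Gapdh and Hprt as covariates of the signals it was 0.53 higher (adjusted p = 0.0073). Of 3 ossification genes, Vegfa, an angiogenic factor, was lower by -0.31 ± 0.11 and 1 passed when adjusted over the list alone, while Col1a1 had a difference of -0.17. Timp3, an inhibitor of matrix proteases and the list's single tested member, was 0.66 ± 0.21 higher. It also passed over the list alone, but for 1 gene this is no adjustment and adds nothing. Of 7 growth factor and Wnt pathway genes, Bmp2 was 0.51 ± 0.09 and Wnt16 0.43 ± 0.10 higher, with 2 past the threshold when adjusted over the list alone. Neither of 2 cell cycle genes nor the calcification gene Ank passed, with 0 past it adjusted over the list alone in both lists. Among 61 other panel genes, 21 were higher and 5 lower. Rrp15, which acts in ribosome biogenesis, was 0.67 ± 0.09 higher, GOs2 0.66 ± 0.15, the interleukin receptor gene Il1rl2 0.56 ± 0.09 and Bcl3, a regulator of NF-kappaB, 0.56 ± 0.12. Csmd1 was 0.53 ± 0.09, Fam105a 0.49 ± 0.09, Smyd3 0.46 ± 0.07, Cdk5rap3 0.42 ± 0.10 and Fam81a 0.38 ± 0.08 higher. The signal of Fam81a lay under 3 times the blank, at 1.62 times it. Gda, a guanine deaminase, was lower with a difference of -0.49 ± 0.15, as were Rasl11b with -0.41 ± 0.11 and Snx11 with -0.27 ± 0.10.

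The median of all genes lay 0.22 above 0, and with each well of the deposited values centred on its median 25 genes passed, 12 higher and 13 lower. Scaling the signals by Gapdh and Hprt left 2 calls, Stab2 but not Acan (1.52 ± 0.49) among them, and turned Bmp2, Wnt16 and Fam81a lower; without scaling 2 passed, Acan and Comp, and Gda, Rasl11b, Vegfa and Snx11 were higher. Of named genes past the threshold in right knees, Vegfa lost its call or its sign in 15 of 24 alternatives, Snx11 in 14, Timp3 in 9, Gda in 7, Comp in 5, Fam81a in 5 of 23, Acan and Stab2 in 1 each and the others in 4 or fewer.

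**Figure D2:**
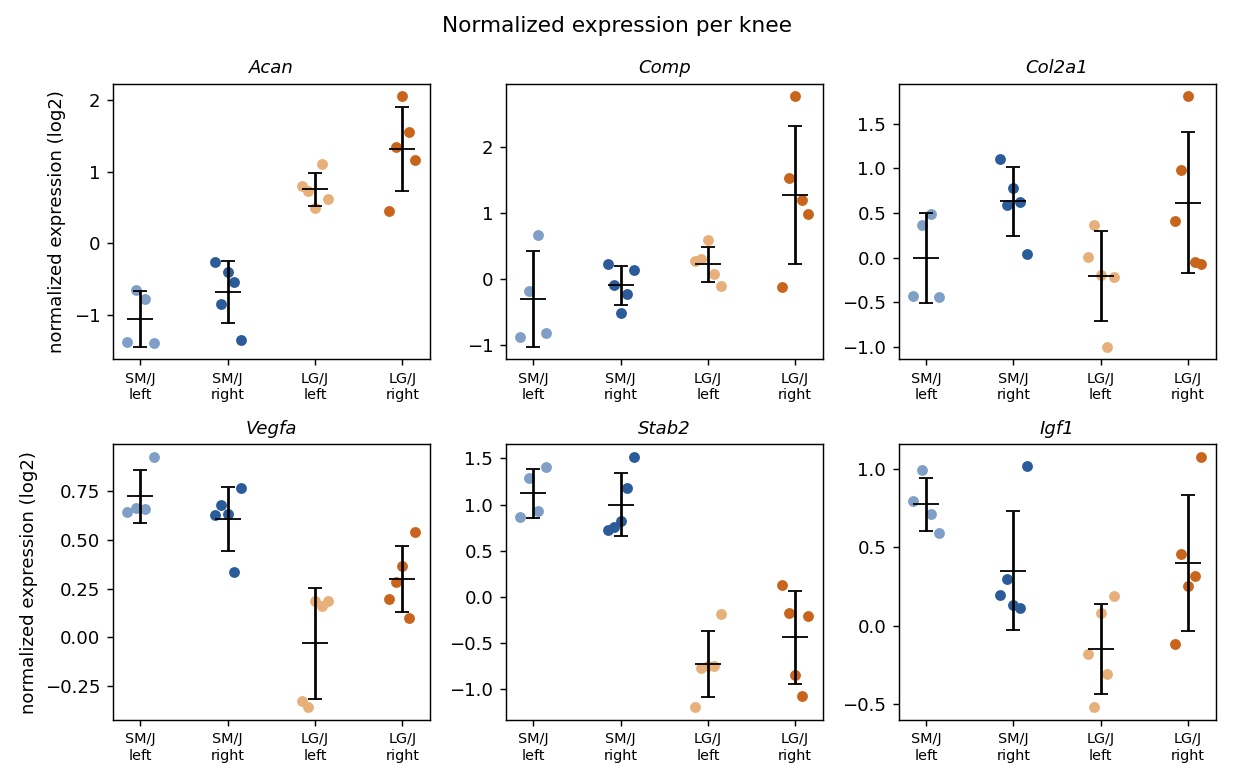
Normalized log2 expression of 6 genes by strain and side; points are knees and bars mean and SD. Acan was higher in LG/J right knees by 2.00 and in left knees by 1.81, while Stab2 lay lower in both, by -1.44 and -1.85.

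In left knees, Stab2 was lower in LG/J mice by -1.85 ± 0.17 (adjusted p = 6.63e-08, limma, n = 5 and 4). Acan was 1.81 ± 0.17 higher (adjusted p = 6.63e-08). Igf1, insulin-like growth factor 1, was lower by -0.92 ± 0.14 and Vegfa by -0.75 ± 0.14. In all, 24 genes passed, 12 higher and 12 lower.

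Of 3 cartilage matrix genes 1 passed as higher, also when adjusted over the list alone; Comp had a difference of 0.53, which was 0.33 without SM/J replicate 1 and 0.85 and past the threshold without SM/J replicate 4, and also passed at 0.50 with Gapdh and Hprt as covariates; Col2a1 had a difference of -0.20, from -0.35 to -0.01 over the alternatives. Vegfa was the ossification gene that passed, with 1 also when adjusted over the list alone. Of 7 growth factor and Wnt genes, Bmp2 was 0.36 ± 0.13 higher and Igf1 lower, and 2 passed when adjusted over the list alone. Timp3 was 0.44 ± 0.11 higher, and its pass over the list alone again involved no adjustment, with 1 gene tested. Ank had a difference of -0.25 and did not pass, nor did either cell cycle gene, with 0 adjusted over the list alone. Of 61 other panel genes 9 were higher and 10 lower. Higher were GOs2 (0.73 ± 0.13), Rrp15 (0.59 ± 0.11), Fam105a (0.49 ± 0.12), Il1rl2 (0.49 ± 0.12), Csmd1 (0.42 ± 0.15) and Postn, a matrix protein of periosteum (0.48 ± 0.16). Lower were Gda (-0.68 ± 0.13), Copz2 (-0.68 ± 0.11), Rasl11b (-0.62 ± 0.14), Snx11 (-0.51 ± 0.12), Nfe2l1 (-0.46 ± 0.13), Sp2 (-0.39 ± 0.13) and Mrpl10 (-0.38 ± 0.11).

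Signals scaled by Gapdh and Hprt gave 9 calls in left knees, 4 higher and 5 lower, and unscaled signals 2, with Acan among them. Bmp2 lost its call in 12 of 23 alternatives, Sp2 in 10, Postn and Mrpl10 in 8 each, Csmd1 in 7 and Nfe2l1 in 5, and the other named genes past the threshold in 4 or fewer.

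The strain differences of the right and left knees were compared across genes. Of 26 genes higher in right and 12 in left knees, 10 were shared, against 4 for independent lists; of 6 and 12 lower genes, 6 were shared, against 0.923. The shared lower genes included Stab2, Gda, Vegfa, Rasl11b and Snx11, but the right-knee calls of Vegfa and Snx11 were lost or changed sign in 15 and 14 of 24 alternatives. No gene passed in opposite directions. Differences correlated across genes with r = 0.92, but genes are not independent replicates and the knees came from the same mice.

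**Figure D3:**
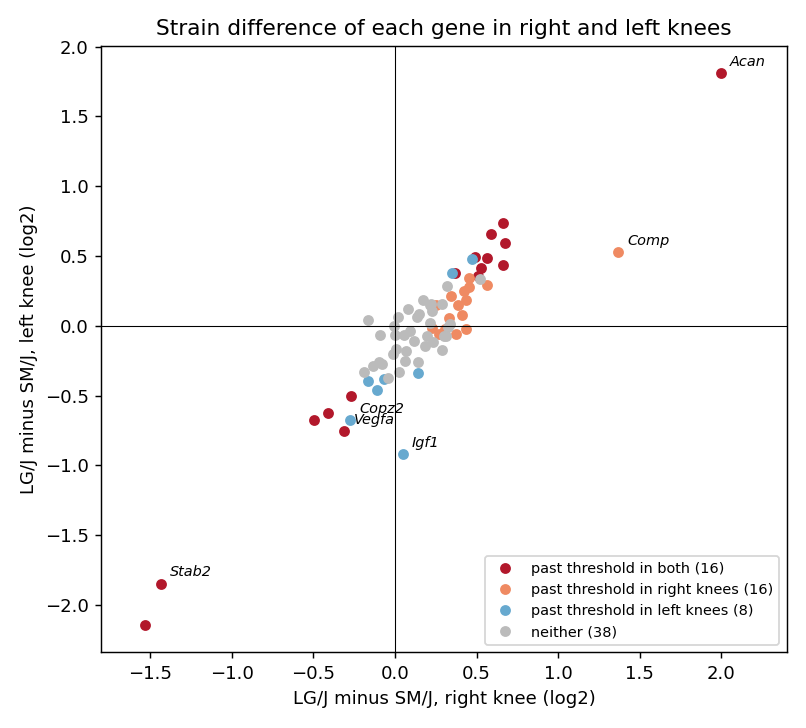
Log2 difference between LG/J and SM/J in right knees (x) and left knees (y) for 78 genes; colours give where a gene passed the threshold. Acan lies at 2.00 and 1.81, Stab2 at -1.44 and -1.85, and Igf1 at 0.05 and -0.92.

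Over both knees, with mouse as a random block, Acan was 1.91 ± 0.18 and Comp 0.97 ± 0.28 higher in LG/J mice, while Stab2 was lower by -1.63 ± 0.16 (limma, 10 LG/J and 9 SM/J knees). In all, 38 genes passed, 28 higher and 10 lower. Other genes that were higher included GOs2 (0.70), Rrp15 (0.63), Timp3 (0.56), Il1rl2 (0.53), Fam105a (0.49), Csmd1 (0.48), Postn (0.47), Bmp2 (0.44), Bcl3 (0.44), Smyd3 (0.40) and Wnt16 (0.32). Gda (-0.58), Vegfa (-0.52), Rasl11b (-0.51), Copz2 (-0.46) and Snx11 (-0.38) were lower. Of cartilage matrix genes 2 of 3 passed, and 2 adjusted over the list alone, with Col2a1 at -0.10. Col1a1 at -0.07 did not pass, and Vegfa was the 1 ossification gene past the threshold, also adjusted over the list alone. Of the growth factor and Wnt list 2 of 7 passed, and 2 adjusted over the list alone. Among 61 other panel genes 23 were higher and 9 lower. Scaled signals gave 17 calls, 7 higher and 10 lower, unscaled signals 3 and median-centred signals 21, 13 higher and 8 lower. The deposited values centred on the well median gave 33, 15 higher and 18 lower. Wnt16 lost its call or its sign in 8 of 25 alternatives and Postn in 5, and the other named genes past the threshold in 3 or fewer.

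Right and left knees of the same mouse were compared within each strain. In SM/J mice, Col2a1 and Col1a1, the main collagen of bone, were each 0.64 ± 0.14 higher in the right knee (paired fit, adjusted p = 0.000396, higher in 4 of 4 mice), and 2 of 78 genes passed, with 7 at an unadjusted p under 0.05. Acan had a difference of 0.41 and Igf1 of -0.41. Of cartilage matrix genes 1 of 3 passed, and 2 adjusted over the list alone; of ossification genes 1 of 3 passed, and 1 adjusted over the list alone. The fit gave all genes the same SE of 0.14, pooled over genes, so its p-values do not measure a gene's own spread between mice. Over the 4 mice the difference ran from 0.14 to 1.54 for Col2a1 and from 0.22 to 1.14 for Col1a1. With no replicate block 0 genes passed, and without SM/J replicate 1 the count was 0, with 0.34 for Col2a1, 0.48 for Col1a1 and 0.18 for Acan. Without SM/J replicate 5 Col2a1 did not pass at 0.70 and Igf1 passed at -0.69, and without SM/J replicate 3 Igf1 was -0.26. Col2a1 lost its call or its sign in 11 of 17 alternatives, and Col1a1 in 9. Of 7 growth factor and Wnt genes 0 passed, with 1, Igf1, adjusted over the list alone.

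In LG/J mice 0 of 78 genes passed the paired fit in limma, with 10 at an unadjusted p under 0.05. Comp had a difference of 1.05 ± 0.27 (adjusted p = 0.108), higher in the right knee in 4 of 5 mice, Col2a1 of 0.82 ± 0.22 in 5 of 5, Igf1 of 0.55 ± 0.15 in 5 of 5 and Acan of 0.56 ± 0.21 in 4 of 5. Adjusted over the list alone, 3 of 3 cartilage matrix genes passed, as did 1 growth factor and Wnt gene, Igf1. Ank, the 1 tested calcification gene, passed only at an unadjusted p under 0.05, since a list of 1 gene involves no adjustment. Without LG/J replicate 1 the count was 4, with 1.41 for Comp, 0.93 for Col2a1, 0.67 for Igf1 and 0.79 for Acan. Without LG/J replicate 3 it was 3, with 0.76 for Comp, 0.53 for Col2a1 and 0.64 for Igf1, and Acan did not pass at 0.31.

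Over both strains, Col2a1 was 0.74 ± 0.17 higher in right knees (paired fit, adjusted p = 0.048, higher in 9 of 9 mice), the 1 gene to pass, with 5 at an unadjusted p under 0.05. Acan had a difference of 0.50 ± 0.15, Col1a1 of 0.48 ± 0.15, Comp of 0.67 ± 0.25 and Hoxb9 of 0.25 ± 0.07. The signal of Hoxb9 lay under 3 times the blank, at 1.48 times it. Adjusted over the list alone, 3 of 3 cartilage matrix genes and 1 of 3 ossification genes passed. The call for Col2a1 ended with no replicate block, where 0 genes passed, and in 16 of 23 alternatives in all, among them those without SM/J replicate 1 (0.64), 3 (0.79) or 5 (0.78) and without LG/J replicate 2 (0.76) or 4 (0.72). Without LG/J replicate 1 Acan passed at 0.60.

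Whether the right-left difference itself differed between strains was tested on 5 LG/J and 4 SM/J mice. By limma 0 of 78 genes passed and 10 had an unadjusted p under 0.05. Exact permutation tests also gave 0, but their smallest possible p is 0.00794. A few genes at that p cannot pass adjustment over 78 genes, so this 0 adds little. Adjusted over the list alone, 1 ossification gene, Vegfa, and 1 growth factor gene, Igf1, passed. Igf1 had a difference of 0.95 ± 0.26 (adjusted p = 0.188), with means of 0.55 in LG/J and -0.41 in SM/J mice; Vegfa had 0.46 ± 0.17 and Trpm3 0.45 ± 0.15. The count was 1, Igf1, without SM/J replicate 5 (1.23), without LG/J replicate 1 (1.07) or without LG/J replicate 3 (1.05).

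Scores over the tested members of a list were compared by exact tests. These members were 3 genes for cartilage matrix, 3 for ossification and 7 for growth factor and Wnt. In left knees Acan and Vegfa were the only cartilage and ossification members past the threshold, so those scores lean on single genes. The cartilage matrix score was 1.12 higher in LG/J right knees (exact permutation p = 0.0159, adjusted p = 0.0492) and 0.71 higher in left knees (exact permutation p = 0.0238, adjusted p = 0.0492), and 0.64 higher in right than in left knees (exact sign-flip p = 0.0273, adjusted p = 0.0492). The ossification score was lower in LG/J left knees by -0.27 (exact permutation p = 0.00794, adjusted p = 0.0492) and 0.23 higher in right than left knees (exact sign-flip p = 0.0234, adjusted p = 0.0492), though median-centred signals turned the latter to -0.09; its right-knee strain difference was -0.08. The growth factor and Wnt score differed by 0.16 in right knees, -0.13 in left knees and 0.09 between sides, none past the threshold, and it turned to -0.48 in right knees with signals scaled by Gapdh and Hprt. All scores that passed share the adjusted p of 0.0492, which the largest p among them sets (exact sign-flip p = 0.0273, cartilage matrix between sides). They thus pass or fail together. With signals scaled or centred on the well median, 0 list scores passed.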

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

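The tests of the Acan and right-knee patterns were chosen after the results were seen; the counts over other splits were planned before they were run.

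In right knees 26 genes were higher and 6 lower in LG/J mice. Of 100 splits of the 10 mice, the real split included, 1 gave as many genes, and the highest of the others gave 0. This argues against chance for the count of 32 genes. The splits counted genes in either direction, so the excess of higher genes was not itself tested against chance. A linear trend with Gapdh and Hprt as the whole cause is argued against, since with both signals as covariates 82.6% of calls were still higher. That evidence is weak, because mean Gapdh and Hprt signals were themselves higher in LG/J right knees, so covariates and strain overlap in part. Signal near the blank is argued against too, with 79.3% higher among genes at 3 times the blank or more. Scaling by Gapdh and Hprt, though, gave 0 higher and 2 lower. Centring each well of the deposited values on its median also ended the excess of higher calls. That centring moved the median difference of all genes from 0.22 to 0.03. Centring pulls this median toward 0 by construction, so it cannot decide whether the excess is real. RNA amounts that Gapdh and Hprt do not track were not tested and stay open, as does a strain difference, which was not tested apart from these.

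Acan was higher in LG/J knees while Col2a1 was not in the main fits. In right knees Col2a1 was 0.53 higher with Gapdh and Hprt as covariates and, without passing, 1.07 higher in unscaled signals. Its right-knee sign turned in 8 of 24 alternatives. More of the same cartilage in LG/J sections would raise cartilage genes alike. Relative to Comp, the Acan signal within a knee was 0.89 log2 units higher in LG/J mice (exact permutation p = 0.0159). That is under the 1 log2 unit asked for to exclude more cartilage as the whole cause, so the ratio cannot decide it. The ratio also pools unlike sides. Mean log2 Comp signal was 11.7 in LG/J and 9.28 in SM/J right knees, and 10.3 and 9.79 in left knees. In left knees mean log2 Col2a1 signal was 11.1 in LG/J and 11.4 in SM/J mice, against 7.31 and 5.53 for Acan. In right knees mean log2 Col2a1 signal was 12.3 and 11.2, against 8.38 and 5.49 for Acan. More cartilage as the cause or a part of it stays open, since Comp was itself higher in LG/J mice, as was mean Col2a1 signal in right knees. The normalization is argued against over both knees by signals centred on the well median, which gave 1.77 for Acan (adjusted p from 1.2e-10 to 0.0269 over the alternatives for both knees). In right knees alone, scaling by Gapdh and Hprt ended the Acan call, with 1.52 ± 0.49 against 2.00 ± 0.28, a lower difference with a wider error. A sequence variant under the Acan probes cannot be told apart from a strain difference in expression, since 0 probe sequences are in the tables used here; a variant under the Stab2 probes was not tested either.

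In left knees 24 genes passed and 1 of 100 splits gave as many, with 18 in the highest other split; over both knees 38 passed, 1 of 100 splits gave as many and the highest other gave 22. The splits argue against chance for both counts. For the side comparison over both strains 7 of 100 sign flips gave 1 gene or more, with 5 as the highest other; chance cannot be excluded. For the strain difference in the right-left difference the real count was 0, which all 100 splits must reach, so they decide nothing about chance; the highest other gave 5. Counts of 5 where the real ones were 1 and 0 may point to a structure among the knees, which was not tested. Flips were too few for a share under 0.05 within strains: 8 in SM/J, where 3 gave 2 genes or more with 2 as the highest other, and 16 in LG/J, where 16 gave 0 or more with 1 as the highest other.

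Single knees stood apart from their group in 6 of 116 gene and group sets tested, and chance alone flags about 1 in 20. By the share of the group's range taken by the gap, these were GOs2 in LG/J right replicate 3 (0.728), Wnt16 in SM/J right replicate 5 (0.715), Csmd1 in SM/J right replicate 5 (0.868), Csmd1 in LG/J left replicate 4 (0.791), Vegfa in SM/J left replicate 5 (0.920) and Igf1 in SM/J right replicate 5 (0.790).

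Trpm3 was higher in the right knee of 5 of 5 LG/J mice and lower in that of 4 of 4 SM/J mice with both knees, though by 0.05 and 0.01 in SM/J replicates 4 and 5, a difference of 0.45 that did not pass the test of the difference (adjusted p = 0.325); its signal lay under 3 times the blank.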

How the results depend on the processing

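The covariate fits, the centring of deposited values and the splits by Hprt signal were chosen after seeing the data. Over all alternatives, values of named genes past the threshold stayed on their side of it in 1183 cases, lost the call in 222 and changed sign in 19; values of named genes not past it stayed so in 375, gained a call in 18 and changed sign in 36. Acan kept direction and call under every alternative run for left knees and for both knees, but in right knees scaling by Gapdh and Hprt ended its call (adjusted p = 0.102, from 8.4e-07 to 0.102 over 24 alternatives). The planned pseudocount could not be applied to values already on a log scale, and exact sign flips cannot pass within a strain, since the smallest p is 0.125 in SM/J and 0.0625 in LG/J mice. Over both strains the smallest sign-flip p is 0.00391, at which a gene alone cannot pass adjustment over 78 genes. The loss of the Col2a1 side call under exact tests thus says little. Except where stated, the cause was not tested. The low signal of 23 genes limits what can be said of them, and leaving them out brought no count outside 1.5 times except the side comparison over both strains, with 0.

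Signals scaled by Gapdh and Hprt gave 2 genes in right knees, 9 in left knees and 17 over both, against 32, 24 and 38. Signals without scaling gave 2, 2 and 3, and signals centred on the well median 10, 12 and 21. Technical replicate 1 alone gave 19 in right knees, and exact permutation 18 in right and 13 in left knees. Knees with low Hprt signal gave 22 over both sides and those with high Hprt signal 19, from fewer knees. Leaving out each mouse gave 19 to 31 genes in right knees (19 without SM/J replicate 1 or LG/J replicate 4), 17 to 29 in left knees and 27 to 41 over both. For the sides in SM/J, where 2 passed, scaled, unscaled and median-centred signals, technical replicate 1 alone, no replicate block, 1 fit over all knees and both covariate fits gave 0, robust limma gave 1, and leaving out a mouse gave 0 to 3. In LG/J, where 0 passed, signals with covariates gave 2 and leaving out a mouse 0 to 4. Over both strains, where 1 passed, technical replicate 2 alone gave 2, leaving out a mouse gave 0 to 2, and these gave 0: scaled, unscaled and centred signals, the low-signal filter, robust limma, exact permutation, no replicate block, 1 fit over all knees, both covariate fits and centred deposited values. For the strain difference in the right-left difference leaving out a mouse gave 0 to 1. Mouse numbers name different animals in LG/J and SM/J, so the main fits did not pair them. Same-numbered mice correlated from -0.31 to 0.28. This range overlaps that of paired knees and cannot by itself exclude a link by number. With the number as a replicate block 23 genes passed in right knees and 20 in left knees.

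Signs turned as follows. Scaled by Gapdh and Hprt, right-knee differences were -0.076 for Bmp2, -0.47 for Wnt16 and -0.53 for Fam81a, Wnt16 over both knees was -0.15, the SM/J side difference of Igf1 was 0.026 and the Trpm3 difference between strains -0.64. Unscaled, right-knee differences were 0.94 for Gda, 0.36 for Rasl11b, 0.72 for Vegfa, 0.93 for Snx11, 1.07 for Col2a1 and 0.71 for Col1a1, the left-knee Col1a1 -0.021, those over both knees 0.17 for Gda, 0.0079 for Vegfa, 0.25 for Snx11, 0.44 for Col2a1 and 0.37 for Col1a1, and the SM/J side differences -0.13 for Col2a1 and -0.19 for Col1a1. Centred on the well median, Wnt16 was -0.33 and Fam81a -0.39 in right knees, Wnt16 over both knees -0.044, Col1a1 between sides over both strains -0.076 and Trpm3 -0.55. With covariates, Col2a1 was 0.53 and Col1a1 0.33 in right knees, 0.10 and 0.14 over both knees, and in SM/J sides Col1a1 was -0.47, Acan -0.57 and Igf1 0.68; with the blank also subtracted these were 0.53, 0.32, 0.10, 0.13, -0.44, -0.63 and 0.34, and Col2a1 was -0.028. With the mouse block, Col1a1 in left knees was -0.086. Over both sides, Col1a1 was 0.054 in low-Hprt knees and Col2a1 0.35 in high-Hprt knees.

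With a mouse left out, the differences, never past the threshold, ranged from -0.31 to 0.16 for Col2a1 and -0.45 to 0.028 for Col1a1 in right knees, from -0.086 to 0.18 for Col1a1 in left knees, and over both from -0.26 to 0.078 for Col2a1 and -0.21 to 0.10 for Col1a1. List scores for cartilage matrix were 0.74, 0.72 and 0.56 for right knees, left knees and sides with scaled signals, and 0.88, 0.78 and 0.34 with centred signals, none past the threshold. The ossification scores in left knees and between sides were -0.26 and 0.13 with scaled and -0.20 and -0.093 with centred signals. The growth factor and Wnt score in right knees turned to -0.48 with scaled and -0.34 with centred signals and to -0.025 with centred deposited values, its side difference turned to -0.046 with centred signals, and its left-knee difference passed at -0.14 with centred deposited values.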

Other observations

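Some strain differences fell in sets of neighbouring panel genes, each starting within 2 Mb of the next in the reference, with other genes possibly between. With 38 of 78 genes past the threshold over both knees, some neighbouring calls are to be expected. Other sets held calls in both directions, such as Timp3 (0.56) with Stab2 (-1.63) and Rasl11b (-0.51) with Fip1l1 (0.20). Il1rl2 (0.53), Il1r2 (0.43) and Map4k4 (0.30), a group that includes genes of interleukin-1 family receptors, were each higher in LG/J mice over both knees, and the fourth gene of the set, Aff3, had 0.13 and did not pass. Casd1 (0.28), Sgce (0.27), Ppp1r9a (0.37) and Pon1 (0.36) were higher too, while the fifth gene of their set, Pon2, had 0.11 and did not pass. Ppp1r9a and Pon1 had signals under 3 times the blank, at 2.2 and 1.54 times it. In right knees of LG/J mice Pon1 was at 1.498 in replicate 5 and at 0.12 or less in the others. With each of 10 mice left out, Pon1 lost its call in 6 cases (0.35, 0.35, 0.39 and 0.32 without SM/J replicates 1, 2, 3 and 5, and 0.39 and 0.19 without LG/J replicates 3 and 5), Il1r2 in 5 (0.36, 0.41 and 0.41 without SM/J replicates 1, 2 and 4, and 0.32 and 0.28 without LG/J replicates 1 and 4), Sgce in 3 (0.23 and 0.24 without SM/J replicates 1 and 4, and 0.25 without LG/J replicate 4) and Map4k4 in 1 (0.24 without SM/J replicate 1). These genes were picked after their values were seen, and no test of neighbours was run on them.

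The column headed fold change in the authors' deposited table equals the LG/J mean divided by the SM/J mean of log10 values, so it is not a ratio of expression. Of 78 entries in the authors' deposited table, 35 are negative, and 27 lie below 1 although the LG/J mean is the higher. In the authors' deposited table, the size of 7 entries exceeds 10, and the largest log2 difference among those genes is 0.48. The authors' deposited table lists 57.0 for Bmp2, 45.6 for Gpatch2 and -45.1 for Pon2.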
